A study of Helianthus annuus with 27 samples.

How the data were processed

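Leaf RNA of sunflower (Helianthus annuus) was sequenced in 27 libraries, which fall into 9 groups of 3 by genotype and by day after rust inoculation. The genotypes are the rust-resistant line carrying the gene R11, labelled WT, and the susceptible mutants S6 and S7; the days are 0, 7 and 14. Every library is labelled as rust-inoculated and none as mock-inoculated, so a change between days joins infection with plant age and sampling time. The labels number the replicates but do not say that they came from separate plants, so p-values measure only the spread between these libraries, which may be technical in part.

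The authors deposited 1 table of estimated counts per gene for the whole series, with whole numbers in all 27 columns and no scaling between libraries. The submitters' processing notes name Trimmomatic 0.38, HISAT2, StringTie and DESeq2 without giving their roles or the versions of the last 3. The genome build, the library type and the use of strand are not given in the sources used here. Counts estimated from transcript models can move between overlapping models, near-identical copies or antisense genes. No gene was checked for these, so a gene at 0 in 1 group and present in another may reflect such a shift. Among low values the count 4 was over-represented, with 26019 cells against 20281 cells of 3 and 13428 cells of 5, and a fit on counts divided by 4 was therefore added.

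The table lists 83726 genes, of which 25924 had no count in any library. The IDs place 83177 genes on 17 numbered chromosomes, 265 on unplaced contigs, 145 in the plastid and 139 in the mitochondrial genome. The files do not pair the IDs with gene names, and 0 IDs matched the RefSeq gene table used here. The gene lists written before the data were examined rest on product names, so their tests and the NLR receptor part of the naming rule were not run. Groups readable from the IDs were used in their place, and these were chosen after the IDs were seen: the chromosomes, the plastid and mitochondrial genes, and stretches of neighbouring genes in the order of their ID numbers. That ID order follows position along a chromosome is an assumption.

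Total counts per library ran from 45222222 to 200394114. No pair of libraries agreed within sampling noise, so each counted as 1 replicate. Counts were rounded, which left them as deposited, and tested with edgeR 4.0.16 in R 4.3.3 by its quasi-likelihood test, with TMM scaling, the filterByExpr filter and 1 mean per group. All 27 libraries entered the fit and shared its estimate of the spread. The filter kept 44010 genes and removed 39716. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called. Levels are CPM with TMM scaling, as mean ± SD over the 3 libraries of a group unless another n is given, and log2 fold changes are given ± their standard error. Against a group at 0 counts, a fold is a lower bound set by a floor of 3 counts over the group's libraries. Such floors cover counting error only.

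Each mutant was compared with WT on each day, each later day with day 0 within a genotype, and S6 with S7 on each day. The difference between a mutant's change from day 0 and that of WT was tested as an interaction. Named genes had a mean of at least 5 CPM in the higher group, were called, did not overlap between the libraries of the groups (outside the interactions), and had the greatest change in the lesser of the contrasts compared (both mutants, all 3 genotypes or both interactions). Without gene names at most 2 IDs in each direction were named per comparison. Genes were also counted when all 18 mutant libraries lay on one side of all 9 WT libraries, and the chromosomes were compared by Fisher's exact test (two-sided, adjusted over 102 tests). The densest stretch was the run of tested genes with the highest score, at 1 for a counted gene and -0.1 for any other, and was set against 1000 shuffles of the genes. Sets of organelle genes were tested with limma 3.58.1 (camera) on log2 CPM with a prior count of 2. This was done with a preset and with an estimated correlation between genes, adjusted over 32 tests. The fry test of limma was also run on these sets, likewise adjusted over 32 tests. It asks whether the genes of a set changed, not whether they changed more than other genes.

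The fit was tested on simulated counts for the comparison of S6 with WT at day 7, with 200 genes changed among 42728. It recovered 38.8% of the genes changed 1.5-fold, 73.1% of those changed 2-fold and 92.4% of those changed 4-fold, and 3.55% of its calls were unchanged genes. The real comparison called 22200 genes. With so few genes changed, the simulation does not show recovery or error where many change and scaling matters. Correlations between libraries are Pearson's r of log2(CPM + 1) with library size scaling, over 28414 genes with a mean of at least 1 CPM.

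Alternatives fixed before the data were examined were DESeq2 size factors, no filter on low counts, the DESeq2 1.42.0 Wald test, a replicate block, fits of only the groups compared, and each library left out in turn. Alternatives chosen after seeing the data were scaling by library size only, counts divided by 4, fits without the libraries that stood apart (S6 day 0 replicate 1, WT day 0 replicate 2, or the other S6 day 0 libraries), and a fit of only the groups compared without S6 day 0 replicate 1. Also added then were fits with the WT libraries of each day divided between the mutants, for the genes both mutants share, and fits without those libraries or with each of the 27 left out in turn, for the organelle sets and the correlations of changes.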

Results

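Rust of sunflower is a fungal leaf disease, and R11 is a gene that gives resistance to it. The series asked how leaf expression differs between a resistant line with R11 (WT) and the susceptible mutants S6 and S7 derived from it. Leaves were sampled 0, 7 and 14 days after inoculation with 3 libraries per genotype and day. Total counts ran from 45222222 in WT day 0 replicate 3 to 200394114 in S6 day 0 replicate 3. The R11 gene itself was not analysed here, since the gene IDs carry no names.

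The libraries grouped by genotype and day, with exceptions among those of day 0. Within the other 8 groups every pair of replicates correlated at r of 0.981 or more. Replicates 2 and 3 of S6 day 0 correlated at 0.993, but replicate 1 correlated with them at 0.940 and 0.942. Replicate 1 lay closest to S7 day 0 (mean r 0.978) and WT day 0 (0.973), whereas replicates 2 and 3 lay closest to S6 day 7 (0.974 and 0.975). The 100 most abundant genes of a library took 18.8% ± 0.070 of its counts in WT day 7, 25.3% ± 1.55 in WT day 0 and 32.3% ± 0.524 in S6 day 7 (SD, n = 3).

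**Figure D1:**
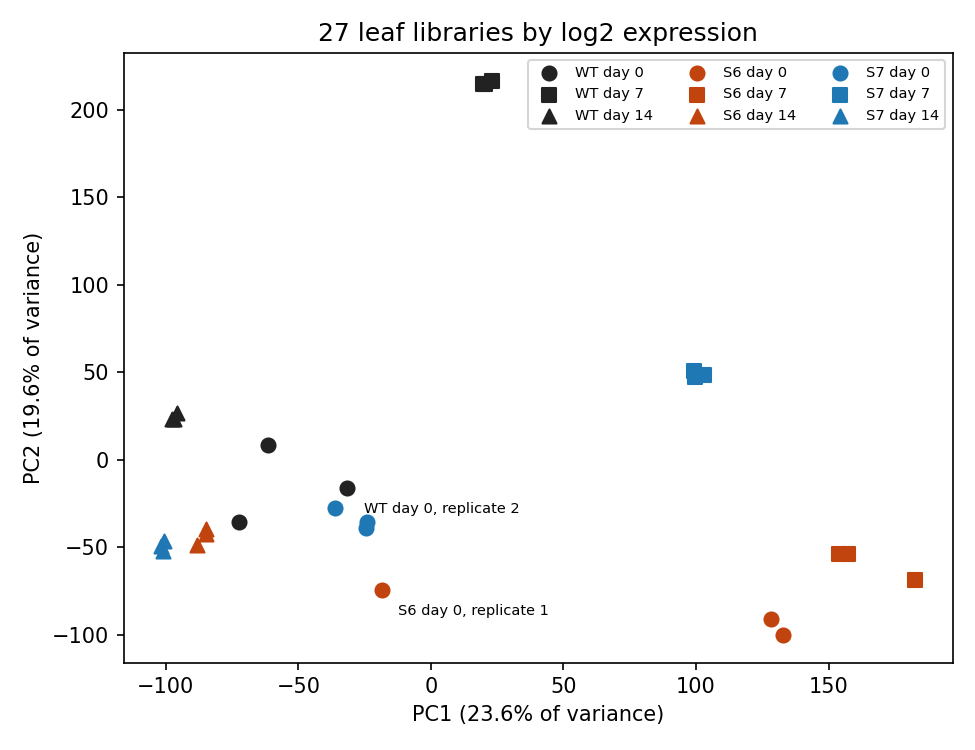
Principal components of log2 expression, PC1 (23.6% of variance) on the x axis and PC2 (19.6%) on the y axis. Each point is 1 of 27 libraries, coloured by genotype and shaped by day; S6 day 0 replicate 1 lies apart from replicates 2 and 3 of its group.

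At day 0 both mutants differed from WT, and which of them had more called genes depended on the S6 libraries and the fit. S7 had 975 genes higher and 1601 lower than WT, and S6 had 7126 higher and 6969 lower (edgeR quasi-likelihood test, adjusted p under 0.05). Chr03g0111071 had 0 counts in WT and reached 10.25 ± 2.09 CPM in S6 and 9.08 ± 1.16 in S7, at least 743-fold and 658-fold higher. Chr06g0244621 was at 15.13 ± 6.29 CPM in WT and at 0 in both mutants, at least 1600-fold lower in S6 and 1620-fold lower in S7. Both mutants shared 687 genes higher and 956 lower than WT, where independent lists would share 157.9 and 253.5. In 3 simulations no gene differed between genotypes and 0 were shared, which was nearly certain in advance. They do not measure the overlap that the shared WT libraries create when many genes are called. With the WT libraries divided between the mutants in all 6 ways (1 for one, 2 for the other, the lone library assumed to vary like the rest), 158 to 300 were shared higher and 253 to 449 lower. Independent lists would then share at most 55.5 and 82.3. The S6 count rested on how its 3 libraries were used: it was 440 when only the 6 libraries compared entered the fit, 15488 in that fit without S6 day 0 replicate 1, and 4084 with replicate 1 as the lone S6 library. In the first and last of these S6 had fewer genes than S7, which had 1650 and 4496. Without S6 day 0 replicate 3 it was 9244. The S7 count of 2576 fell to 1650 when only the groups compared were fitted, to 1656 without S7 day 0 replicate 2 and to 1678 without replicate 3, and was 5804 without S6 day 0 replicate 1 and WT day 0 replicate 2. The 1643 shared genes became 1090 without WT day 0 replicate 1, 1086 without replicate 3, 3024 without S6 day 0 replicate 1, 151 when only the groups compared were fitted, and 4309 without S6 day 0 replicate 1 and WT day 0 replicate 2. Scaled by library size only, S6 had 3560 genes higher and 13204 lower.

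At day 7 the mutants were farthest from WT. S6 had 9502 genes higher and 12698 lower, and S7 had 6471 higher and 8078 lower, by the same test. Chr16g0744671 had 0 counts in WT and 11.73 ± 0.579 CPM in S6 and 10.92 ± 0.657 in S7, at least 2010-fold and 1870-fold higher. Chr06g0246731 stood at 27.61 ± 0.631 CPM in WT with 0 counts in both mutants, at least 2170-fold and 2600-fold lower. Chr10g0450191 was seen at 25.74 ± 0.61 CPM in WT at this day, at 0.402 ± 0.696 in WT at day 0 and at 0 in WT at day 14, and had 0 counts in both mutants at day 7. The mutants shared 5134 genes higher and 6027 lower, against 1397.1 and 2330.7 for independent lists. With the WT libraries divided they shared 3171 to 3961 higher and 3070 to 4183 lower, against at most 840.1 and 1307.2. Scaled by library size only, the direction of the calls tilted: S6 had 4179 higher and 23723 lower, S7 had 3707 higher and 16198 lower, and 2527 and 14415 were shared, as the median over all genes moved from -0.14 to -0.74 in S6 and from -0.10 to -0.41 in S7 (log2).

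At day 14 both mutants differed from WT to a like degree. S6 had 5342 genes higher and 6493 lower, and S7 had 6381 higher and 7083 lower. Chr03g0111071 was again higher in both, by 7.90 ± 0.46 log2 in S6 (adjusted p = 1.27e-09) and 8.96 ± 0.46 in S7 (adjusted p = 8.49e-11, edgeR). Chr13g0606731 was at 1.05 ± 0.364 CPM in WT, 43.63 ± 1.52 in S6 and 61.33 ± 0.483 in S7, although WT had held 21.69 ± 3.48 at day 0. Chr06g0244621 and Chr06g0246621 had 0 counts in both mutants and 21.65 ± 0.81 and 12.72 ± 1.03 CPM in WT. The mutants shared 3633 genes higher and 3718 lower, against 774.5 and 1045 for independent lists. With the WT libraries divided they shared 1718 to 2365 higher and 1689 to 2001 lower, against at most 398.7 and 453.

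**Figure D2:**
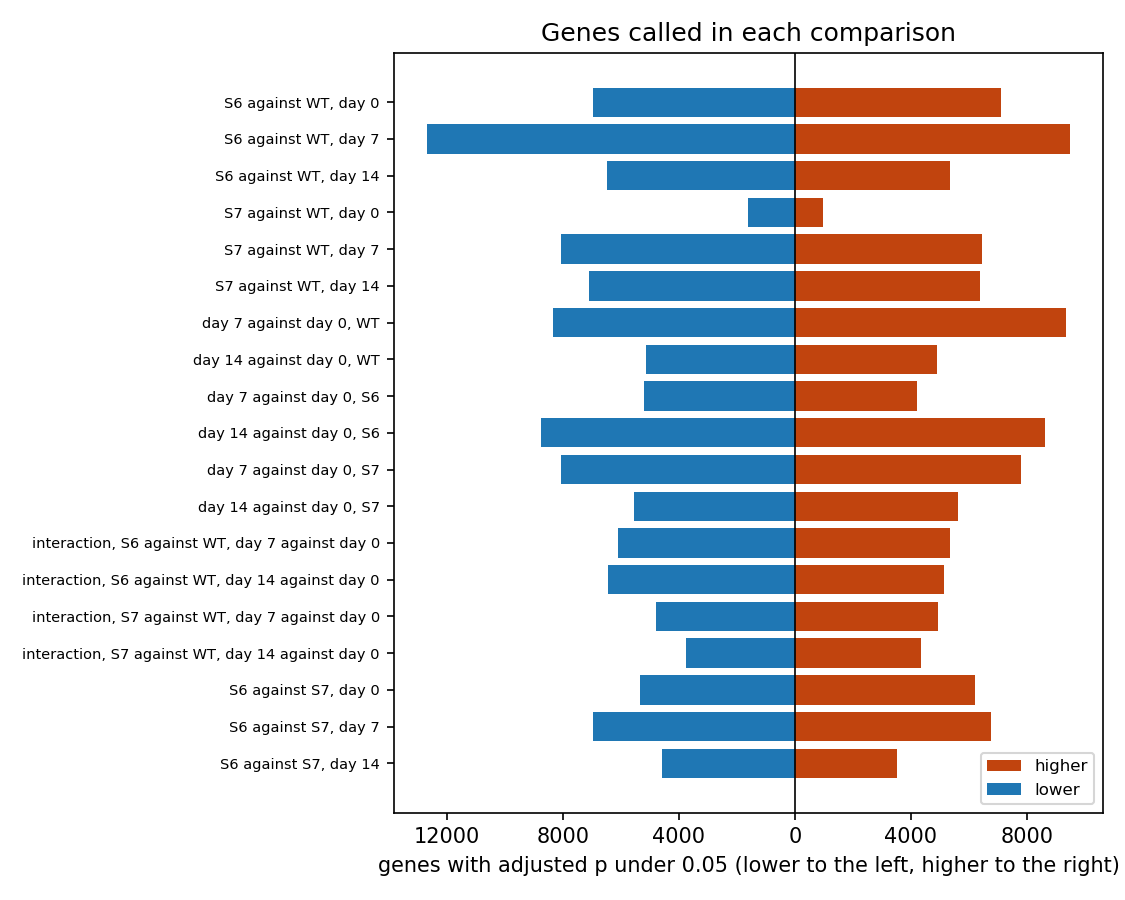
Genes called in each of the 19 comparisons, with genes higher in the first group named (or in the mutant's change) to the right of 0 and lower genes to the left. Counts are genes with an adjusted p under 0.05 in the edgeR fit of 27 libraries; S7 against WT at day 0 has the fewest, 2576, and S6 against WT at day 7 the most, 22200.

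Some genes separated the mutants from WT on every day, and many of these lay close together on chromosome 6. In all 18 mutant libraries 85 genes were lower than in any of the 9 WT libraries, and 92 were higher. Of the 85, 45 were on chromosome 6, which is 1.99% of its 2261 tested genes against 0.0966% elsewhere (Fisher's exact test, odds ratio 20.99, adjusted p = 3.46e-33). They were densest between Chr06g0243411 and Chr06g0245371, where 36 of 141 tested genes were lower in every mutant library (permutation p = 0.001, the smallest that 1000 shuffles can give). Chromosome 13, the chromosome on which R11 is known to map, had 0 of its 2921 tested genes among the 85 (adjusted p = 0.148) and 5 among the 92 (adjusted p = 0.967). If all 27 libraries were exchangeable, a gene would separate 9 from 18 in 2.13e-05% of cases per direction. Libraries of 1 genotype are not exchangeable with the others, so this share does not measure how often lines differ by chance.

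Within that stretch the loss was patchy. Of 101 genes with a WT mean of at least 1 CPM, 16 were under 10% of WT in both mutants (15.8%), and 70 kept 50% of the WT level or more. Elsewhere in the genome 186 of 28385 such genes were under 10% (0.655%). The stretch was chosen for genes lower in every mutant library, so its higher share was built in. The 16 genes were likewise picked by their low mutant level, and their sums only describe them. The 16 genes summed to 70.4 ± 16.7 CPM in WT, 0.222 ± 0.107 in S6 and 0.338 ± 0.172 in S7 (SD, n = 9). The WT value included 1 low library: WT day 0 replicate 2 was at 26.55 CPM, and the other 8 WT libraries lay between 71.15 and 80.14. Without that library 115 genes were lower in every mutant library, 54 of them on chromosome 6. Among the genes higher in every mutant library the densest run was 3 of 3 tested neighbours from Chr03g0111071 to Chr03g0111091 (permutation p = 0.001, the smallest that 1000 shuffles can give).

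**Figure D3:**
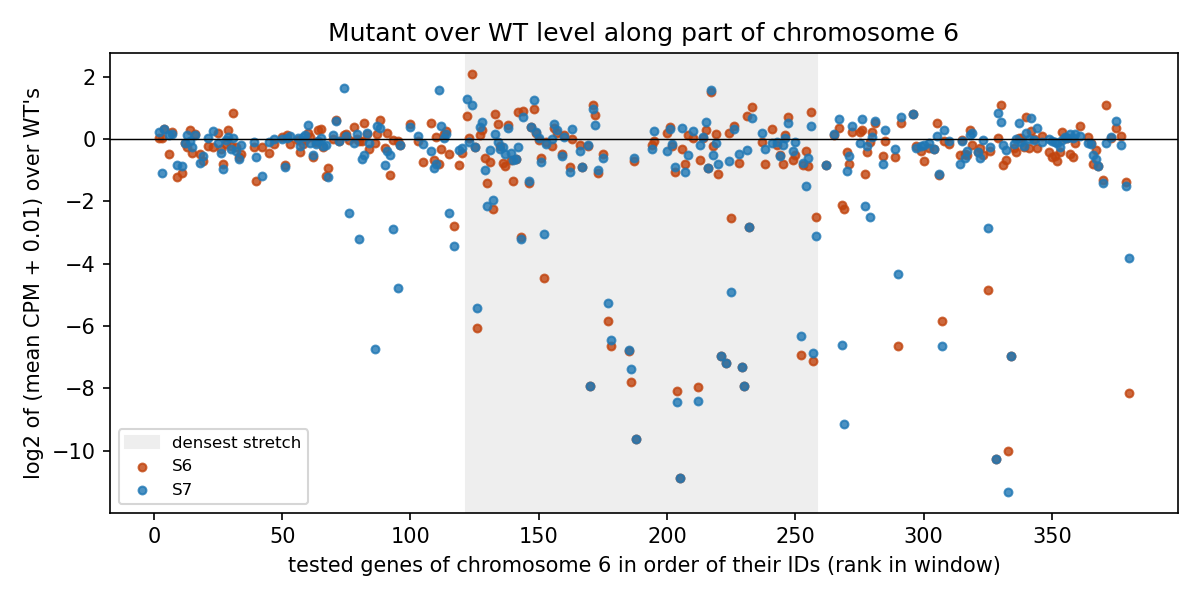
Mean mutant over WT level (log2 of CPM + 0.01) for genes with a WT mean of at least 1 CPM, in ID order along part of chromosome 6, with S6 and S7 as separate points. The shaded stretch of 141 tested genes holds 16 genes under 10% of WT in both mutants, beside 70 at 50% or more.

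Mitochondrial transcripts were higher in S6 than in WT at days 0 and 7. They were a very small share of all counts. At day 0 this share was 0.0155% ± 0.00699 in WT and 0.028% ± 0.00752 in S6 (SD, n = 3). At day 7 it was 0.0110% ± 0.00416 in WT and 0.0305% ± 0.00521 in S6. As the library type is not given, a difference in captured organelle RNA cannot be told apart from one in expression. Of 107 tested mitochondrial genes, 58 were higher in S6 than in WT at day 0, 89 at day 7 and 34 at day 14, and 0 were lower. With the preset correlation the set test called the mitochondrial genes on all 3 days (adjusted p = 1.74e-19, 6.66e-20 and 1.92e-10, camera). The set test with an estimated correlation, used from here on unless the preset or fry is named, gave adjusted p = 0.0352 at days 0 and 7. At day 14 it gave adjusted p = 0.17. The fry test called the set on all 3 days (adjusted p = 2.82e-07, 1.58e-09 and 0.000104, fry). At day 14 replicate 2 of S6 stood apart, with summed mitochondrial levels of 304.8, 664.3 and 338 CPM in S6 beside 317.6, 303.4 and 383.5 in WT. Without it 28 genes were higher (adjusted p = 0.264, camera). Without S6 day 0 replicate 1 the set was called (adjusted p = 0.0497), as it was without that library and WT day 0 replicate 2 (adjusted p = 0.00606). With an estimated correlation the call at day 14 thus rests on the libraries used. In S7 against WT the mitochondrial set was not called at days 0, 7 or 14 with an estimated correlation (adjusted p = 0.411, 0.851 and 0.981, camera). Nor was it with any of the 27 libraries left out in turn (lowest adjusted p = 0.166). With the preset correlation it was called lower at day 0 (adjusted p = 2.5e-06) but not at days 7 and 14 (adjusted p = 0.384 and 0.949). The fry test also called it at day 0 (adjusted p = 0.0233, fry) but not at days 7 and 14 (adjusted p = 0.953 and 0.837). S6 was compared with S7 gene by gene only, without the set test. With DESeq2 size factors 80, 80 and 25 of 107 mitochondrial genes were higher in S6 at days 0, 7 and 14, and 0 were lower. Scaled by library size only, 76, 76 and 28 were higher and 0 lower. At day 0 the summed mitochondrial level of S6 was uneven, with 200.1 CPM in replicate 1 and 442.6 and 403.6 in the others, beside 224.5, 149.8 and 85.48 in the WT libraries, and with replicate 1 as the lone S6 library 18 genes were higher (adjusted p = 0.027). Of 108 plastid genes, 52 were higher in S6 than in WT at day 0, 78 in S6 at day 7 and 29 in S7 at day 7, with 0 lower. The plastid set was called with the preset correlation (adjusted p = 1.69e-10, 1.37e-14 and 9.92e-08, camera). It was not called with an estimated correlation (adjusted p = 0.467, 0.411 and 0.468). The fry test called it in all 3 comparisons (adjusted p = 0.00552, 3.74e-05 and 0.0233, fry). The first count was 4 with S6 day 0 replicate 1 as the lone S6 library, and the last was 19 without WT day 7 replicate 1, 16 without WT day 7 replicate 2, 14 without S7 day 7 replicate 3 and 44 without S6 day 0 replicate 1. At day 14 no plastid gene was higher, with 10 lower in S6 and 35 lower in S7. Again the set was called with the preset correlation (adjusted p = 0.0124 and 1.22e-06, camera) and not with an estimated one (adjusted p = 0.701 and 0.468). The fry test called it in S7 (adjusted p = 0.0135, fry) but not in S6 (adjusted p = 0.208). Summed plastid levels were uneven there too, at 2876, 11570 and 3253 CPM in S6 beside 4964, 5497 and 7828 in WT, and the 10 lower genes were 12 without S6 day 14 replicate 2 (adjusted p = 0.417), 5 without WT day 14 replicate 3 and 16 without S6 day 0 replicate 1. Scaled by library size only, 49, 79 and 34 mitochondrial genes were higher in S6 at days 0, 7 and 14 with 0 lower, and for plastid genes 44 were higher and 1 lower in S6 at day 0, 57 and 0 in S6 at day 7, and 12 and 3 in S7 at day 7.

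From day 0 to day 7 leaves of all 3 genotypes changed. WT had 9341 genes higher and 8355 lower at day 7, S6 4223 and 5218, and S7 7791 and 8078. Chr16g0729831 and Chr14g0665501 rose in every genotype: the first went from 0.578 ± 0.501 to 28.18 ± 0.518 CPM in WT, from 0.183 ± 0.0567 to 17.65 ± 7.79 in S6 and from 0.0956 ± 0.0831 to 8.984 ± 0.748 in S7, and was back at 0.263 ± 0.185 CPM or less at day 14. Chr17g0822341 fell in every genotype, from 388 ± 93.8 to 7.968 ± 0.616 CPM in WT and from 819.1 ± 157 to 141 ± 6.34 in S7. In all 3 genotypes 1905 genes were higher and 2065 lower, against 158.7 and 181.8 for independent lists, which here share no libraries, and 387 were called in all 3 in differing directions. The S6 count of 9441 was 853 when only the groups compared were fitted, 5178 in that fit without S6 day 0 replicate 1, and 15005 with that replicate as the lone S6 day 0 library; the 3970 genes common to all genotypes became 531 and 6314 in the first and last of these. With library size scaling only, WT had 14500 genes higher and 4818 lower and the common genes were 2421 higher and 1462 lower.

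From day 0 to day 14 WT had 4908 genes higher and 5145 lower, S6 8640 and 8753, and S7 5636 and 5560. Chr16g0766071 and Chr06g0274881 rose in all 3 genotypes, and the second reached 20.12 ± 0.743 CPM in WT, 24.61 ± 1.62 in S6 and 14.69 ± 0.324 in S7. Chr08g0317891 fell in all 3, with log2 changes of -4.26 ± 0.25 in WT, -4.47 ± 0.25 in S6 and -4.37 ± 0.25 in S7 (adjusted p = 2.81e-11, 2.38e-11 and 2.18e-11, edgeR). The genotypes shared 1169 genes higher and 1345 lower, against 123.4 and 129.3 for independent lists, and 1185 were called in all 3 in differing directions. The S6 count of 17393 was 7139 when only the groups compared were fitted and 6087 with S6 day 0 replicate 1 as the lone S6 day 0 library; with library size scaling only, S6 had 16070 higher and 4225 lower.

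The change by day 7 differed between the mutants and WT, and in most of the genes shared by both mutants WT itself had a called change. The interaction was called for 5365 genes higher and 6108 lower in S6, and for 4926 higher and 4781 lower in S7. Both mutants shared 3271 higher and 3056 lower, against 600.5 and 663.5 for independent lists. With the WT libraries divided 1540 to 1973 were shared higher and 1014 to 1505 lower, against at most 281.1 and 209.6. Of the 3271, WT had a called fall in 2812, and neither mutant had a called change in 1174 of these. Of the 3056, WT had a called rise in 2661, with neither mutant called in 1199. Both interactions subtract the same WT change, so genes called in both tend to be those in which WT changed. These shares were thus partly built in, and they were not counted with the WT libraries divided. Chr10g0448251 dropped in WT from 23.19 ± 1.24 to 0.0174 ± 0.0168 CPM and stood at 63.07 ± 16 in S6 and 35.39 ± 0.533 in S7 at day 7. Chr07g0311211 rose in WT from 0.0327 ± 0.0318 to 5.29 ± 0.385 CPM while both mutants were at 0.0572 ± 0.0611 and 0.0532 ± 0.0398. Chr16g0744671 was also called, but the call was lost in both mutants without WT day 0 replicate 2, the only WT day 0 library that held it (log2 0.41 in S6 and 0.73 in S7 without it, adjusted p = 1 by edgeR). The S6 count of 11473 was 6856 when only the groups compared were fitted. Scaled by library size only, the interaction had 2796 higher and 10813 lower in S6, 2793 and 10257 in S7, and 1732 and 7085 in both.

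By day 14 the interaction was called for 5155 genes higher and 6440 lower in S6 and for 4348 higher and 3758 lower in S7. Both mutants shared 2721 and 2430 of these, against 509.3 and 549.9 for independent lists. With the WT libraries divided 759 to 1444 were shared higher and 394 to 924 lower, against at most 187.7 and 197.5. WT had no called change in 990 of the 2721 and 1110 of the 2430. WT fell and both mutants rose in 784 of the 2721, and WT rose and both mutants fell in 211 of the 2430. These counts too come from interactions that share the WT change. Chr10g0442381 went from 35.5 ± 10.3 to 3.908 ± 0.275 CPM in WT, from 8.978 ± 6.5 to 68.77 ± 2.67 in S6 and from 6.512 ± 1.68 to 56.36 ± 1.12 in S7. Chr07g0280141 and Chr07g0280151 were lower in the mutants' change than in that of WT, although their mean levels were higher in both mutants on every day. WT was near the floor at day 0, with 14 and 17 counts over its 3 libraries. Chr07g0280141 went from 0.056 ± 0.0871 to 1.313 ± 0.264 CPM in WT. It went from 23.53 ± 17.4 to 23.86 ± 0.874 CPM in S6 and from 69.03 ± 2.34 to 55.78 ± 1.99 in S7. The S6 count of 11595 was 6456 when only the groups compared were fitted, 18193 without S6 day 0 replicate 1, and 4378 with that replicate as the lone S6 day 0 library, where the calls on Chr07g0280141 and Chr07g0280151 were lost in S6 (log2 -1.56 and -1.42, adjusted p = 0.405 and 0.436, edgeR). Without both S6 day 0 replicate 1 and WT day 0 replicate 2 the counts were 18847 in S6, 12337 in S7 and 8822 in both; scaled by library size only, S6 had 9220 higher and 3187 lower and S7 3379 and 4608.

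The mutants also differed from each other, and a run of neighbouring genes on chromosome 4 was high in S6 alone. Between Chr04g0146491 and Chr04g0146631, 14 of 15 tested neighbours were higher in every S6 library than in any WT or S7 library (permutation p = 0.001, the smallest that 1000 shuffles can give). Their summed level was 80.8 ± 9.83 CPM in S6, 3.16 ± 1.1 in WT and 4.48 ± 1.4 in S7 (SD, n = 9), 25.6-fold over WT and 18.04-fold over S7. The remaining gene, Chr04g0146501, stood at 99.4 CPM in S6, 110 in WT and 106 in S7. S7 alone had its own low genes on chromosome 6: 15 of its 44 lay there (Fisher's exact test, adjusted p = 1.39e-07), 8 of them among 27 tested genes from Chr06g0242731 to Chr06g0243051. In ID order this run lay just before the chromosome 6 stretch low in both mutants. Counted from Chr06g0241571, the run ended at tested gene 102 and the stretch began at tested gene 121, Chr06g0243411. Whether the run and the stretch share a cause was not tested.

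S6 against S7 gave 6222 genes higher and 5353 lower at day 0, 6753 and 6972 at day 7, and 3522 and 4590 at day 14. Chr09g0393001 had 0 counts in S7 at day 0 against 9.895 ± 2.31 CPM in S6, at least 1060-fold higher. Chr04g0153861 had 0 counts in S6 at day 7 against 21.46 ± 1.77 CPM in S7, and Chr14g0634281 had 0 counts in S6 at day 14 against 25.01 ± 1.25 in S7, at least 1690-fold and 2700-fold lower. The day 0 count of 11575 was 415 when only the groups compared were fitted, 18527 without S6 day 0 replicate 1, 7046 without replicate 2, 6948 without replicate 3, 3132 with replicate 1 alone, and 19008 without S6 day 0 replicate 1 and WT day 0 replicate 2. The day 14 count of 8112 was 15118 when only the groups compared were fitted and 12355 without those same libraries of day 0. Scaled by library size only, S6 had 2726 genes higher and 12371 lower at day 0, 2890 and 12633 at day 7, and 4524 and 2758 at day 14.

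**Figure D4:**
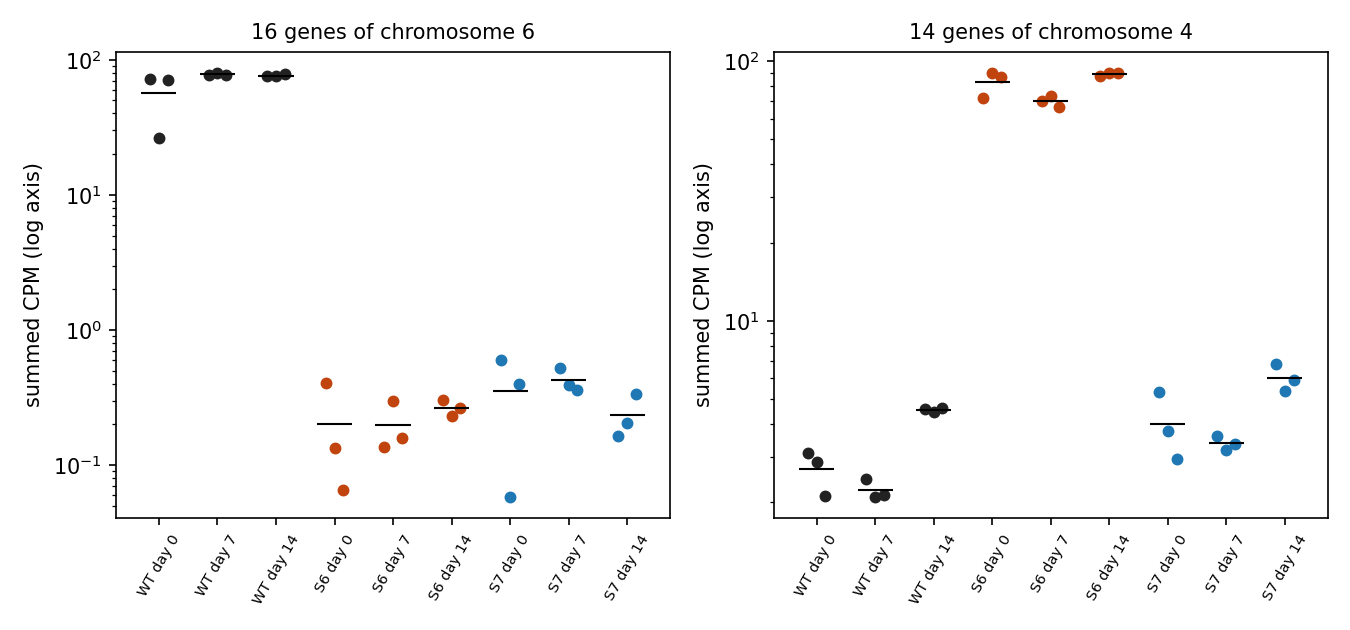
Summed CPM per library, on a log axis, of the 16 chromosome 6 genes under 10% of WT in both mutants (left) and of the 14 chromosome 4 genes high in S6 (right). Points are the 3 libraries of each group and lines their means; WT day 0 replicate 2 is the low WT point at 26.55 CPM on the left, and all 9 S6 libraries lie between 66.58 and 90.19 CPM on the right.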

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

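The days changed expression differently in the mutants than in WT, by a test of the difference itself, the interaction in the edgeR fit of 27 libraries. It was called for 11473 genes in S6 at day 7, 11595 in S6 at day 14, 9707 in S7 at day 7 and 8106 in S7 at day 14. The splits of the libraries given here were chosen only after these counts were seen. Each used 40 splits of the 12 libraries, the real one included, in fits of those libraries alone. At day 7, 2 of 40 splits gave as many genes as the real one in S6 (real 6856, highest other 17528) and 2 of 40 in S7 (real 13095, highest other 13507). At day 14, 1 of 40 splits was as large in S6 (real 6456, highest other 1060) and 1 of 40 in S7 (real 10020, highest other 9347). The highest other count came each time from a split that kept a real group of 3 libraries together, and no split that kept none together called more than 2 genes. Shuffling genotypes within a day also breaks up the differences between genotypes that all days share. The counts thus turned on which real groups a split kept, so these splits cannot decide for or against chance on either day.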

How the results depend on the processing

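Scaling by library size only, counts divided by 4 and the fits without 2 libraries of day 0 were chosen after seeing the data. So was the fit of only the groups compared without S6 day 0 replicate 1. The fits with divided WT libraries, and all left-out fits for organelle sets and correlations of changes, were also added then. The other alternatives, with each library left out in turn for the counts, were fixed before the data were examined. With each library left out in turn 308 of 318 counts stayed within 1.5 times, and with the other settings 232 of 258 did. The DESeq2 Wald test, DESeq2 size factors, no filter, counts divided by 4 and the replicate block moved no count by more. Replicate numbers did not pair the libraries (108 pairs with a shared number, mean r 0.00054), so the replicate block served only as an alternative and not as a paired design. Of 1232 values of named genes 1216 kept direction and call, 16 lost the call and 0 reversed, with 4 lacking a DESeq2 adjusted p left out. These genes were named for large called changes in the same data. Their stability was thus largely built in and does not speak for other called genes. The planned gene list tests, with all of their alternatives, were not run, since no ID matched a product name. Where 1 library was left in a group, it was assumed to vary like the other groups. The cause of the shifts that follow was not tested.

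With only the groups compared, the counts were, for S6 against WT at day 0, 440; S7 against WT at day 0, 1650; S6 at day 7, 853, and at day 14, 7139, against day 0; the S6 interactions, 6856 at day 7 and 6456 at day 14; S6 against S7, 415 at day 0 and 15118 at day 14; both mutants at day 0, 151; and all 3 genotypes at day 7, 531. Without S6 day 0 replicate 1 in such a fit, S6 at day 7 against day 0 had 5178. Without S6 day 0 replicates 2 and 3 the counts were 4084 for S6 and 4496 for S7 against WT at day 0, 15005 and 6087 for S6 at days 7 and 14 against day 0, 4378 for the S6 interaction at day 14, 3132 for S6 against S7 at day 0 and 6314 for all 3 genotypes at day 7. Without S6 day 0 replicate 1 and WT day 0 replicate 2 they were 5804 for S7 against WT at day 0, 4309 for both mutants at day 0, 18847 and 12337 for the S6 and S7 interactions at day 14, 8822 for both of these, and 19008 and 12355 for S6 against S7 at days 0 and 14. Library size scaling gave 16942 genes in both mutants at day 7.

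With each library left out in turn, the ranges that passed 1.5 times were 9244 to 19988 for S6 and 1656 to 2692 for S7 against WT at day 0, 8652 to 18193 for the S6 interaction at day 14, 6948 to 18527 for S6 against S7 at day 0 and 1086 to 3024 for both mutants at day 0.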

Other observations

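The changes from day 0 were more alike between the mutants than between either mutant and WT at day 14, while at day 7 the order rested on the S6 day 0 libraries. Across 28414 genes, which are not independent replicates, the log2 change by day 7 correlated at r of 0.664 between S6 and S7 (rho 0.660), 0.550 between WT and S7 (rho 0.565) and 0.340 between WT and S6 (rho 0.438). By day 14 r was 0.576 between S6 and S7 (rho 0.623), 0.385 between WT and S7 (rho 0.187) and 0.375 between WT and S6 (rho 0.218). Without S6 day 0 replicate 1 r between S6 and S7 was 0.393 at day 7, below the 0.550 between WT and S7, and 0.495 at day 14; with that replicate as the lone S6 day 0 library it was 0.712 and 0.514. At day 14 the rho of WT with S7 fell to 0.111 and that of WT with S6 to 0.109 without WT day 0 replicate 2, and the latter was 0.145 without S6 day 0 replicate 1 and 0.428 with it as the lone S6 day 0 library. The rho of S6 with S7 at day 7 was 0.360 without S6 day 0 replicate 1. Mitochondrial genes in S7 were higher at day 14 than at day 0 for 44 of 107, with 0 lower. That set was called with the preset correlation (adjusted p = 8.48e-13, camera). With an estimated correlation it was not called (adjusted p = 0.115), but was without S6 day 0 replicate 1 (adjusted p = 0.0298). The fry test called it with all libraries (adjusted p = 2.49e-05, fry).

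All tests that follow were chosen after the results were seen. Genes of 1 stretch of chromosome 6 were lower in every mutant library. Of 100 splits of the libraries 1, the real one, gave as many such genes in the genome (real 85, highest other 0). The other splits mixed the genotypes, so a low count was built in and chance differences between lines were not tested. S6 alone had 275 genes lower and 234 higher than in all other libraries, and S7 alone 44 and 63. Loss of the whole stretch from the mutants is argued against, since 69.3% of its expressed genes stood at 50% of WT or more in both mutants. The score that set its ends lets in unchanged genes, so this share does not bear on loss of smaller parts. Scaling between libraries is argued against, since 46 chromosome 6 genes separated the mutants with library size scaling only. Another haplotype, read poorly against 1 reference, may account for such a patchy loss and stays open: 2 genes of the stretch were higher in every mutant library, which does not decide it. The run of genes low in S7 alone lay just before the stretch in ID order, and its bearing on a haplotype was not tested. A mutation that lowers some genes of the stretch stays open too and was not tested.

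WT day 0 replicate 2 was low in the genes the mutants lack: 24 genes nearly absent from all 18 mutant libraries, 21 of them on chromosome 6, were at 33.7% of their level in the other WT day 0 libraries. RNA of S6 or S7 as the whole cause is argued against, as a mixture would need 66.3% mutant RNA, while 11 transcripts nearly absent from the other 8 WT libraries stood at 5.11% ± 3.65 (jackknife SE over genes) of their mutant level, the highest at 28.6% and 6 at 0 counts. A smaller share stays open, as these 11 summed to 3.565 CPM there and 0.4811 and 0.4439 in the other WT day 0 libraries. Chr16g0744671, which WT day 14 also held, was nearer the mutant level. It was at 5.579 CPM there and 0 in those 2, beside 8.798 ± 1.59 in S6 and 6.59 ± 0.585 in S7 at day 0. On log2 CPM with TMM scaling and a prior count of 2, replicate 2 was as close to S7 day 0 (mean r 0.9589) as to its own group (0.9588). Replicates 1 and 3 were closer to their own group (0.9599 and 0.9563) than to S7 day 0 (0.9533 and 0.9463). Scaling or depth is argued against, as 75 other expressed genes of the stretch were at a median of 92.5%. Plants of mixed genotype at this stretch, or RNA of another line, may be present and stay open, untested.

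S6 day 0 replicate 1 stood apart from replicates 2 and 3. Depth is argued against: thinned to 45216985 counts in the genes tested, its highest r with them was 0.941, below 0.981, the lowest within any other group. A wrong genotype label is argued against, as 375 genes chosen for S6 without these 3 lay above every WT and S7 library for 81.1% or more in each (at most 11.7% with a WT or S7 day 0 library in their place), and an exchange with an S6 library of day 7 or 14 is argued against, as the lowest r within those groups was 0.986. A day 7 or day 14 library under a day 0 label is argued against by genes that set 1 day apart in WT and S7: at most 48.4% of 5187 lay on the side of day 7 in any of the 3 (62.7% or more in S6 day 7), and at most 14.9% of 1554 on that of day 14 (83.5% or more in S6 day 14). Sampling at a time other than labelled may account for it and cannot be told apart from a difference between plants. Over the 5187 genes replicates 2 and 3, at 47.8% and 48.4%, lay between replicate 1 at 6.65% and S6 day 7. That midway position depended on the genes used. With a 2-fold cutoff between groups (228 genes), replicates 2 and 3 were at 18.42% and 17.98%. Replicate 1 was then at 2.632% and S6 day 7 at 50% or more. With a 4-fold cutoff (17 genes) all 3 were at 0%, against 47.06% in each S6 day 7 library.

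Other splits of the 6 libraries compared were counted for 15 comparisons in fits of those libraries alone. The 10 splits are too few for a share under 0.05, and 1 of 10, the real one, was as large in each. Real and highest other counts were, at days 0, 7 and 14, 440 and 1, 22663 and 0, and 16511 and 1 for S6 against WT, and 1650 and 1, 19804 and 0, and 18069 and 1 for S7 against WT. For S6 against S7 they were 415 and 2, 13881 and 2, and 15118 and 1. Against day 0, at days 7 and 14, they were 19301 and 0, and 9911 and 2 in WT, 853 and 2, and 7139 and 0 in S6, and 17934 and 1, and 14938 and 1 in S7. Genes called the same way in both mutants were counted in fits of all libraries of a day. The real counts there differ from those of fits of only the groups compared (151 at day 0). On each day 1 of 40 splits, the real one, was as large: 193 at day 0 (highest other 1), 13061 at day 7 (highest other 9330, in a split that kept 1 real group of 3 together, and 0 in splits that kept none) and 11218 at day 14 (highest other 1). Most other splits mixed the genotypes, so low counts were built in and chance differences between lines were not tested.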
